A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

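Gene expression was measured in budding yeast on 16 spotted 2-colour arrays, 4 for each of 4 mutants: set1, H3K4A, the double mutant set1htz1 and the triple mutant set1htz1sir2. Per the deposited description, a mutant culture and a paired wild-type culture were grown in rich medium with added tryptophan and adenine and harvested at an OD600 of 0.7. Every array carried mutant cDNA in one dye and wild-type cDNA in the other, and the dyes were exchanged between the 4 independent biological replicates. In each group the mutant was in Cy5 on arrays 1 and 3 and in Cy3 on arrays 2 and 4, per the labels. The deposited description says that mRNA was labelled for set1, set1htz1 and set1htz1sir2 and total RNA for H3K4A, whereas the labels give polyA RNA for every array. That conflict was left open, so a comparison of H3K4A with another mutant can carry a difference in RNA input.

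The authors quantified spots with GenePix 3.0, removed spots of low signal or with a regression R2 under 0.75, and normalized the ratios to the total signal in each sample, per the deposited description. The deposited table holds 1 log2 ratio of mutant over wild type per spot and array. The base was settled from the values: on every array, 100% of the distinct values that could tell the bases apart were whole steps of a ratio under base 2, within 0.05 of a step for H3K4A and 0.0051 for the others. There were 145 to 215 such values on the H3K4A arrays and 1 to 27 on the others. The direction is that of the deposited description. The lowest ratio that could be written for set1, set1htz1 and set1htz1sir2 was 0.01, so a log2 value of -6.64 is a floor. No sign was turned here. The H3K4A arrays with the mutant in Cy3 had already been turned by the authors. Genome build and probe sequences are not given in the sources used here, and scanner intensities were not used here.

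The table had 6282 entries, of which 296 repeat or extend an ORF name with the prefix z, whose meaning is not given in the sources used here. Entries of the same ORF were averaged, which left 6074 genes. A RefSeq gene table of assembly R64 served only for names, gene order and coding length. It matched 5539 genes, of which 5031 had a symbol of their own, and the other 535 kept the name in the files. Between 5385 and 5802 entries per array had a value. Array medians lay between -0.04 and 0.03, and the SD of an array's log2 ratios between 0.248 and 0.640. The number of arrays per group limits the precision.

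The ratios were used as deposited, with no further normalization. limma 3.58.1 in R 4.3.3 fitted all 16 arrays at once, with 4 group means and 1 dye term per gene that the groups share, followed by empirical Bayes moderation. A gene was tested if it had a value on at least 3 of the 4 arrays of every group, which held for 5147 genes. Calls needed a Benjamini-Hochberg adjusted p under 0.05. Comparisons with wild type test a group mean of ratios against 0. By the description each ratio has a paired wild-type culture, so that wild type enters only through the ratios. The comparisons between mutants set their ratios to wild type against each other. Adjusted p-values of genes are limma's, and errors written after ± are its standard errors unless an SD is named. The dye term was called for 1009 genes. The dye effect was larger in set1 (SD across genes 0.306) than in H3K4A (0.149), set1htz1 (0.148) and set1htz1sir2 (0.169), correlated between groups from 0.267 to 0.603, and differed between groups for 124 genes. Arrays of set1 correlated from 0.729 to 0.791 within a dye and from -0.261 to 0.0964 across dyes. For H3K4A these ranges were 0.0874 to 0.358 and -0.285 to 0.616, for set1htz1 0.798 to 0.858 and 0.664 to 0.831, and for set1htz1sir2 0.925 to 0.927 and 0.768 to 0.815.

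Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over 182 tests of 26 lists in 7 comparisons, and again with an estimated correlation. The lists were COMPASS subunits, the SWR1 complex, histones, genes flanking the silent mating loci, haploid-specific, a-specific and pheromone response genes, the COS and PAU families, the phosphate, galactose and iron regulons, ergosterol synthesis, ribosomal proteins, ribosome biogenesis, general stress, heat shock, amino acid synthesis, sulfur amino acid synthesis, DNA damage response, meiosis, NAD and thiamine synthesis, respiration, glycolysis, marker genes and subtelomeric genes. The deleted genes, SIR proteins, alpha-specific genes and genes of the silent mating loci had fewer than 3 tested members and are given gene by gene. Subtelomeric genes are those with the 10 outermost systematic ORF names of a chromosome arm, because no build is named; 251 of them were tested. Their share among calls was tested with a 2-sided Fisher exact test, adjusted over 14 tests.

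Design, lists, comparisons and alternatives were chosen before the data were examined. Genes named in the text are, for each comparison, the deleted genes, up to 8 of the largest rises and 8 of the largest falls among called genes whose arrays all lie on one side of 0 or of the other group, and up to 4 members of each called list. Members of near-identical families, such as PAU, COS, THI5, THI11 and THI12 and Ty ORFs, cannot be separated without the probe sequences and are uncertain as single genes. Results of some single genes are not reported here. Alternatives were other scalings, other filters, no dye term, the array number as a block, averaged pairs of arrays, separate fits, robust moderation, other thresholds and windows, and each array left out in turn. Another 4 alternatives were added after seeing the data: a dye term for each group, entries with the prefix z left out, a trend on coding length removed, and PAU and COS genes left out.

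The fit was tested on simulated data built on the spread of the 5147 genes, with 200 changed genes in 10 runs. For set1 against wild type it found 11.8% of 1.2-fold, 90.7% of 1.5-fold and 99.8% of 2-fold changes, and for set1htz1sir2 against set1htz1 2.84%, 50.3% and 96.4%. False calls made up 5.48% and 5.25% of the calls in those simulations.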

Results

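The series holds 16 2-colour arrays of mutant against wild-type RNA from growing yeast cultures, 4 arrays for each of 4 mutants. Set1 is the enzyme that methylates lysine 4 of histone H3, and H3K4A carries an alanine in place of that lysine. HTZ1 encodes the histone variant H2A.Z, and SIR2 encodes the histone deacetylase of silent chromatin. The mutants allow 3 questions to be asked: whether loss of the enzyme and loss of its target residue change the same genes, what loss of H2A.Z adds to loss of Set1, and which changes of the double mutant need SIR2. Of 5147 genes tested, 970 changed in set1, 216 in H3K4A, 2445 in set1htz1 and 2596 in set1htz1sir2.

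The deleted genes were low where the labels place the deletions. The log2 ratio of SET1 was -2.67 ± 0.42 (SD, n = 4) in set1, -2.34 ± 0.45 in set1htz1 and -2.31 ± 0.22 in set1htz1sir2. In H3K4A it was -0.14 ± 0.15, with no call. SIR2 fell by 2.44 ± 0.28 in set1htz1sir2 and lay at -0.14, -0.17 and -0.10 in set1, H3K4A and set1htz1, with no call. HTZ1 had a mean log2 ratio of -2.94 ± 0.26 in set1htz1, 0.34 ± 0.21 in set1 and 0.03 ± 0.22 in H3K4A, and had no value in set1htz1sir2, which left it outside the test. Whether the probes lie inside the deleted parts is not known.

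**Figure D1:**
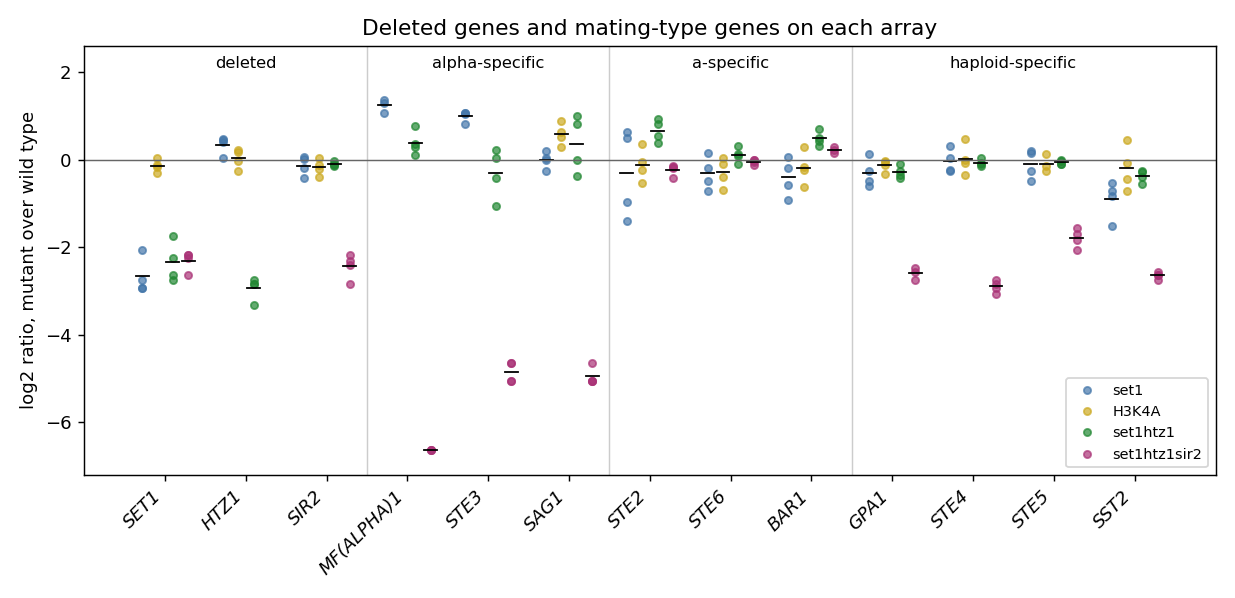
Log2 ratios of mutant over wild type on each array (points, at most 4 per group) and their group means (bars) for deleted, alpha-specific, a-specific and haploid-specific genes. Alpha-specific and haploid-specific genes were low in set1htz1sir2, where SAG1 averaged -4.96 and STE4 -2.90, while the a-specific genes stayed near 0.

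In set1, 466 genes rose and 504 fell, mostly by little: 32 rose and 3 fell by 2-fold or more. Which direction held more genes depended on the analysis: 48.0% of the called genes rose here, 55.3% with each array centred on its median and 57.0% without replicate 4. The largest rises were those of IRC18 (2.14 ± 0.13), the NAD synthesis gene BNA2 (1.91 ± 0.11), the arginine synthesis gene ARG1 (1.87 ± 0.17), and YMR244W (1.85). Next came the chaperone-like gene HSP32 (1.81), the DNA glycosylase gene OGG1 (1.70), YNR064C (1.61) and YOL024W (1.58). Apart from SET1, the largest falls were those of AFB1 (-1.15 ± 0.11), PER33 (-1.09), ATO3 (-0.95), NGK1 (-0.93), the mitochondrial NADH dehydrogenase gene NDE1 (-0.91), the aconitase gene ACO1 (-0.90) and YOR135C (-0.90). The PAU family, cell wall mannoprotein genes that lie mostly near telomeres, rose almost as a whole: 18 of 19 measured members rose (19 adjusted over the list alone), with a median of 0.47, led by PAU20 at 0.66. This held with an estimated correlation (limma camera adjusted p = 5.8e-13, and adjusted p = 0.010 with an estimated correlation).

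Other groups passed in set1 only with the preset correlation. NAD and thiamine synthesis genes rose (9 of 18 rose, 9 rose and 2 fell adjusted over the list alone, adjusted p = 0.17 with an estimated correlation), among them the nicotinic acid transporter gene TNA1 (1.37) and THI5 (1.18) and THI11 (1.16). Amino acid synthesis genes rose (9 of 30 rose and 1 fell; 10 and 1 adjusted over the list alone, adjusted p = 0.32 with an estimated correlation), with ARG3 at 0.96 and HIS4 at 0.81. Among meiosis and sporulation genes 6 of 27 rose and 1 fell (7 and 1 adjusted over the list alone, adjusted p = 0.35 with an estimated correlation). Those that rose included the spore wall genes DIT2 (1.07), DIT1 (0.88) and GAS4 (1.08), and SPS19 (0.98). Of 58 ribosome biogenesis genes 7 rose and 2 fell, the same counts as adjusted over the list alone (adjusted p = 0.45 with an estimated correlation). Leaving out set1 replicate 4 lowered the count of called genes to 595.

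In H3K4A, 185 genes rose and 31 fell, and 10 rose by 2-fold or more against 1 that fell. TRP1, a marker gene in many laboratory strains, was highest (2.15 ± 0.10). Marker genotypes are not given in the sources used here, so that its value is not assigned to the histone mutation. It was followed by HPF1 (1.51 ± 0.13), the histone H3 gene HHT2 (1.46 ± 0.12), the pyrimidine synthesis gene URA1 (1.35), THI5 (1.26), AAD6 (1.12), THI12 (1.11) and the thiamine synthesis gene THI4 (1.09). Histone H3 is the protein mutated in this strain, so the value of HHT2 is not assigned to a response, here or against set1. The largest falls were those of MIC19 (-1.06 ± 0.14), the Ty ORFs YJR028W (-0.77), YJR029W (-0.71) and YCL020W (-0.67), the copper chaperone gene SCO1 (-0.73), YGR115C (-0.70), YFLTYA (-0.64) and ECM27 (-0.57). General stress and storage carbohydrate genes rose: 13 of 30 rose (17 rose and 1 fell adjusted over the list alone, limma camera adjusted p = 5.6e-15, and adjusted p = 0.037 with an estimated correlation). Among them were HSP12 at 0.97, the glucokinase gene GLK1 at 0.92, RTN2 at 0.80 and HXK1 at 0.78. Of 19 PAU genes 10 rose and none fell (17 and 0 adjusted over the list alone, median 0.34, adjusted p = 0.010 with an estimated correlation), with 825 genes of all tested at an unadjusted p under 0.05.

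The other groups called in H3K4A were lost with an estimated correlation. Of 18 NAD and thiamine synthesis genes 7 rose, also over the list alone (adjusted p = 0.076 with an estimated correlation). Of 9 COS genes 4 rose (6 adjusted over the list alone, adjusted p = 0.060 with an estimated correlation), led by COS5 at 0.48. Of 12 genes flanking the silent mating loci the serine and threonine deaminase gene CHA1 (1.04) and the transporter gene GIT1 (0.84) rose (4 adjusted over the list alone, adjusted p = 0.054 with an estimated correlation). Of 7 DNA damage genes 3 rose, among them RNR2 (0.55) and RNR4 (0.38) (3 adjusted over the list alone, adjusted p = 0.088 with an estimated correlation). The chaperone genes HSP26 (0.86), HSP30 (0.65) and HSP104 (0.54) rose among 20 heat shock genes (3 adjusted over the list alone, adjusted p = 0.34 with an estimated correlation). Of 27 meiosis genes 5 rose (6 adjusted over the list alone, adjusted p = 0.31 with an estimated correlation), including DIT1 (0.73) and HOP1 (0.59). SDH4 (0.50) and SDH2 (0.45) rose among 27 respiration genes (4 adjusted over the list alone, adjusted p = 0.20 with an estimated correlation), and TDH1 (0.45) among 10 glycolysis genes (2 adjusted over the list alone, adjusted p = 0.27 with an estimated correlation). Ribosomal protein genes (median -0.15), ribosome biogenesis genes (-0.16) and haploid-specific genes (-0.13) were shifted downward and sulfur genes (0.12) upward, with 0 members called in each by limma among the 825 genes at an unadjusted p under 0.05. Over the lists alone 2 sulfur genes and none of the others passed (adjusted p = 0.54, 0.17, 0.20 and 0.076 with an estimated correlation, in that order). The ribosomal protein shift turned to 0.063 without H3K4A replicate 1. Leaving out replicate 4 lowered the count of called genes to 129, and quantile normalization raised it to 773, of which 57.7% rose against 85.6% as deposited.

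How far set1 and H3K4A change the same genes was asked in a comparison of both with each other. Their log2 changes had a Pearson correlation of 0.195 and a Spearman correlation of 0.135 across genes, which are not independent replicates. The covariance was 0.0111. Simulated groups without effects on arrays of their own gave a mean correlation of -0.0043 and a highest of 0.0175 in 20 simulations, with a mean covariance of -6.3e-05. That noise was drawn for each gene on its own, whereas residuals of set1 and H3K4A arrays correlated from -0.424 to 0.398. The simulation therefore cannot tell whether 0.195 exceeds what genes that move together would give. Of the 185 genes that rose in H3K4A 77 also rose in set1, against 16.7 for independent lists, and 4 fell in both against 3.04. Another 17 genes were called in opposite directions.

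Between H3K4A and set1 themselves 386 genes differed, 211 higher and 175 lower in H3K4A. Of the called genes 54.7% were higher here and 48.7% with each array centred on its median. SET1 (2.53 ± 0.21), TRP1 (1.99), HHT2 (1.79), the stress glycoprotein gene YGP1 (1.41), PRY1 (1.40), HXK1 (1.39), the cell wall gene TIP1 (1.38) and ACO1 (1.36) were the most higher in H3K4A. Most lower there were genes that set1 raises: YOL024W (-1.71 ± 0.30), ARG1 (-1.68), OGG1 (-1.53), IRC18 (-1.42), YMR244W (-1.37), BNA2 (-1.32) and YNR064C (-1.24), along with SCO1 (-1.27). General stress genes were higher in H3K4A (12 of 30; 15 higher and 1 lower adjusted over the list alone, adjusted p = 0.092 with an estimated correlation), with GLK1 at 1.26 and PGM2 at 1.22. Of 30 amino acid synthesis genes 4 were lower (7 adjusted over the list alone, adjusted p = 0.43 with an estimated correlation), HIS4 by -0.90 among them. Of 58 ribosome biogenesis genes 8 were lower (9 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation), with RRP5 at -0.78, and of 121 ribosomal protein genes 1 was lower, RPL32 at -0.96 (1 adjusted over the list alone, adjusted p = 0.54 with an estimated correlation). Heat shock genes (4 of 20 higher, 6 adjusted over the list alone), histones (HHT2 and HHF2, the latter at 0.86; 2 adjusted over the list alone), COS genes (1 of 9, 6 adjusted over the list alone), sulfur genes (1 of 13, 2 adjusted over the list alone) and flanking genes of the silent loci (2 of 12, 2 adjusted over the list alone) were shifted upward. None of these 5 held with an estimated correlation (adjusted p = 0.20, 0.20, 0.15, 0.053 and 0.14, in that order, with an estimated correlation). RNA input may differ between these groups, and leaving out H3K4A replicate 4 lowered the count to 246.

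A total of 2445 genes changed in set1htz1, 1093 up and 1352 down. Of the called genes 44.7% rose here and 50.2% with each array centred on its median. Among the largest rises were the lysine synthesis gene LYS2 (2.65 ± 0.17), BNA2 (2.64 ± 0.11), and the thiamine genes THI11 (2.62), THI12 (2.605) and THI5 (2.51). They were followed by the proline catabolism gene PUT1 (2.495), RTA1 (2.35) and IRC18 (2.27). MET17, a sulfur assimilation gene, fell most (fitted -6.39), but 3 of its 4 arrays are at the lowest ratio the files can hold, so the size of its fall is not known. LYS2, at 0.22 in set1htz1sir2, and MET17 are marker genes in many laboratory strains, and marker genotypes are not given in the sources used here. Their values are therefore not assigned to loss of H2A.Z or Set1. Further large falls were those of SET1, the acid phosphatase genes PHO12 (-1.84) and PHO11 (-1.75), BET2 (-1.62), and the phosphate-regulated genes SPL2 (-1.61), PHM6 (-1.5025) and PHO84 (-1.43). The phosphate regulon fell as a group: 11 of 15 measured genes fell and none rose, also over the list alone, with a median of -0.97 (limma camera adjusted p = 9.4e-06, and adjusted p = 0.010 with an estimated correlation). Respiration genes rose (25 of 27, also over the list alone, median 0.83, adjusted p = 1.1e-11, and adjusted p = 0.040 with an estimated correlation), with the ATP synthase gene ATP16 and the cytochrome bc1 gene QCR8 both at 1.13. DNA damage genes rose (6 of 7, also over the list alone, median 0.52, adjusted p = 0.0014, and adjusted p = 0.038 with an estimated correlation), including the ribonucleotide reductase genes RNR4 (1.09) and RNR2 (0.85).

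Further groups passed in set1htz1 only with the preset correlation. General stress genes rose (22 of 30 and 1 fell; 23 and 1 adjusted over the list alone, adjusted p = 0.094 with an estimated correlation), with HSP12 at 1.63 and HOR7 at 1.46. Of 20 heat shock genes 11 rose, also over the list alone (adjusted p = 0.088 with an estimated correlation), led by HSP26 (1.89), HSP30 (1.72) and the endoplasmic reticulum chaperone gene KAR2 (1.34). Of 19 PAU genes 16 rose, also over the list alone (adjusted p = 0.054 with an estimated correlation), and of 9 COS genes 7 rose and 1 fell, likewise (adjusted p = 0.27 with an estimated correlation). NAD and thiamine synthesis (11 of 18 up, 1 down), amino acid synthesis (14 of 30 up, 1 down, ARG4 at 1.26), meiosis (13 of 27 up, 1 down, SPS19 at 1.41) and galactose genes (4 of 6 up, GAL1 at 1.13) gave the same counts adjusted over the list alone (adjusted p = 0.11, 0.31, 0.31 and 0.088 with an estimated correlation). Ribosome biogenesis genes fell more often than they rose (25 down and 4 up of 58, also over the list alone, adjusted p = 0.52 with an estimated correlation). All 4 measured COMPASS subunits, partners of Set1 in its complex, fell, also over the list alone: SWD3 (-0.85), SWD1 (-0.46), SWD2 (-0.38) and SPP1 (-0.37, adjusted p = 0.17 with an estimated correlation).

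What loss of H2A.Z adds to loss of Set1 was asked with set1htz1 against set1, in which 465 genes were higher and 530 lower. Of the called genes 46.7% were higher here and 50.9% with each array centred on its median. The most higher were LYS2 (2.42 ± 0.22), MOH1 (2.37), PUT1 (2.35), RRT1 (2.12), HXK1 (2.06), the arginine catabolism gene CAR2 (2.04), the DNA end-joining gene LIF1 (1.92) and RTA1 (1.90). The most lower were MET17 (fitted -6.08, its size not known for the same reason), PHO11 (-1.96), PHO12 (-1.90), PHM6 (-1.85), the polyphosphate synthesis gene VTC3 (-1.47), SPL2 (-1.46), ARG1 (-1.39) and GPM3 (-1.29). LYS2 and MET17 can differ by marker genotype here too and are not assigned to loss of H2A.Z. The series has no mutant of HTZ1 alone, and for the other genes too loss of H2A.Z cannot be separated from further strain differences. The phosphate regulon was lower (9 of 15, also over the list alone, median -0.62, adjusted p = 0.0050 with an estimated correlation). Respiration genes were higher (20 of 27, 25 adjusted over the list alone, median 0.68, adjusted p = 0.038 with an estimated correlation), as were heat shock genes (8 of 20, 14 adjusted over the list alone, adjusted p = 0.037 with an estimated correlation, HSP26 at 1.69) and DNA damage genes (3 of 7, 4 adjusted over the list alone, adjusted p = 0.047 with an estimated correlation, RNR2 at 0.69).

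Several groups passed in this comparison with the preset correlation alone. General stress (17 of 30 higher, also over the list alone) and pheromone response genes (5 of 13, 6 adjusted over the list alone, AGA1 at 1.54 and FIG1 at 0.87) were higher (adjusted p = 0.055 and 0.054 with an estimated correlation). NAD and thiamine (6 of 18 higher and 1 lower, 9 and 1 adjusted over the list alone, BNA1 at 1.36), sulfur (4 of 13 higher and 1 lower, 7 and 1 adjusted over the list alone, SUL1 at 0.98) and COS genes (5 of 9 higher and 1 lower, 7 and 1 adjusted over the list alone) were shifted upward (adjusted p = 0.17, 0.057 and 0.20 with an estimated correlation). So were the a-specific (2 of 3 higher, 3 adjusted over the list alone, STE2 at 0.98 and BAR1 at 0.89) and ergosterol genes (3 of 23 higher, 2 adjusted over the list alone, ERG28 at 0.77), with adjusted p = 0.27 and 0.39 with an estimated correlation. Ribosome biogenesis (13 of 58 lower, 14 adjusted over the list alone, ENP2 at -0.88) and COMPASS genes (2 of 4 lower, 4 adjusted over the list alone, SWD2 at -0.48) were shifted downward (adjusted p = 0.22 and 0.14 with an estimated correlation). Leaving out set1htz1 replicate 3 lowered the count of 995 called genes to 655.

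**Figure D2:**
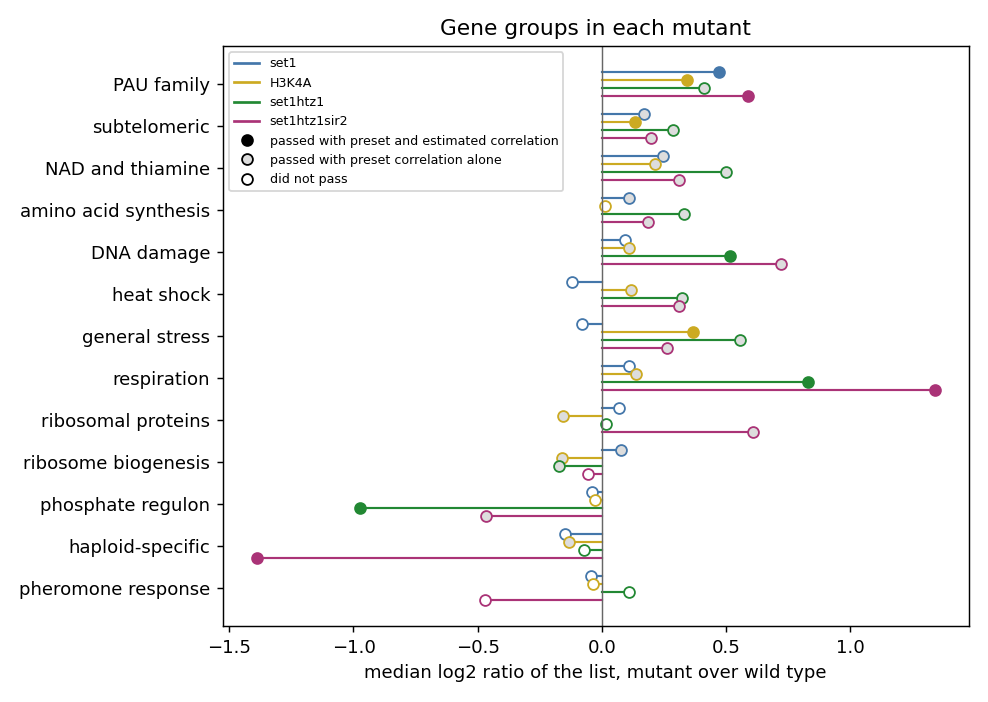
Median log2 ratio of mutant over wild type for 13 gene groups in each of the 4 mutants. Filled points passed with both correlations, grey points with the preset one alone, and open points with neither. The median reached 1.34 for respiration and -1.39 for haploid-specific genes in set1htz1sir2.

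In the triple mutant set1htz1sir2, 1242 genes rose and 1354 fell. Which direction held more genes depended on the analysis: 47.8% of the called genes rose here and 53.5% with each array centred on its median. Genes of mating stood out among the falls: the alpha-agglutinin gene SAG1 (-4.96 ± 0.13), AFB1 (-5.06 ± 0.11), its neighbour YLR041W (-4.25) and the G protein gene STE4 (-2.90) were among the lowest. So were MET17 (-5.89, also near the lowest ratio), LIF1 (-3.16), URA1 (-2.79) and the malate dehydrogenase gene MDH2 (-2.65). Haploid-specific genes, which cells that carry both mating types shut off, fell as a group: 10 of 11 fell, also over the list alone, with a median of -1.39 (limma camera adjusted p = 1.1e-08, and adjusted p = 0.010 with an estimated correlation). SST2 (-2.65), GPA1 (-2.57) and STE5 (-1.79) were among them. Of the alpha-specific genes in the list (SAG1, STE3, MF(ALPHA)1 and MF(ALPHA)2) only SAG1 was tested. STE3 lay at -4.85 ± 0.24 (SD, n = 4), MF(ALPHA)1 at the floor of -6.64 on 3 arrays, and MF(ALPHA)2 had no value. The 3 a-specific genes tested were not called (STE2 -0.23, STE6 -0.05, BAR1 0.22). Of the silent mating loci HMLALPHA1 lay at -2.01 ± 0.29 (SD, n = 4) outside the test, while HMLALPHA2 (-0.10) and HMRA2 (-0.085) were tested without a call. Of the SIR proteins only SIR4 was tested (-0.17, no call). SIR1 lay at -0.36 ± 0.15 (SD, n = 4) and SIR3 had no value.

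The largest rises in set1htz1sir2 were those of YNL337W (2.79 ± 0.14), the cell wall gene HPF1 (2.72 ± 0.13), PUT1 (2.63), the ATP synthase inhibitor gene INH1 (2.59), the protease inhibitor gene PBI2 (2.54), THI12 (2.38), THI11 (2.33) and YNR077C (2.27). Respiration genes rose almost without exception (26 of 27, also over the list alone, median 1.34, adjusted p = 1.7e-16, and adjusted p = 0.019 with an estimated correlation), with QCR8 at 1.89 and ATP16 at 1.75. Of 19 PAU genes 18 rose, also over the list alone (median 0.59, adjusted p = 0.040 with an estimated correlation). Ribosomal protein genes rose (104 of 121, 106 adjusted over the list alone, median 0.61), with RPL41A at 1.56 and RPL32 at 1.33, but adjusted p = 0.28 with an estimated correlation. In this mutant the change of a gene fell with its coding length (Spearman correlation -0.33 across 4756 genes). With that trend removed the medians of respiration and ribosomal protein genes were 1.06 and 0.53.

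Other groups in set1htz1sir2 passed with the preset correlation alone. The phosphate regulon fell (9 of 15 down and 3 up, also over the list alone, adjusted p = 0.092 with an estimated correlation), with PHO12 at -1.76 and PHO5 at -1.08. COS genes (7 of 9; 7 up and 1 down adjusted over the list alone, COS2 at 1.18), DNA damage genes (4 of 7, also over the list alone, RNR2 at 1.08) and heat shock genes (11 of 20 up, 1 down, also over the list alone, HSP26 at 1.54) rose (adjusted p = 0.092, 0.076 and 0.13 with an estimated correlation). General stress (14 of 30 up, 2 down, also over the list alone), NAD and thiamine (11 of 18 up, 4 down, also over the list alone) and amino acid synthesis genes (12 of 30 up and 3 down, 12 and 4 adjusted over the list alone, LEU4 at 0.92) rose more often than they fell (adjusted p = 0.32, 0.38 and 0.47 with an estimated correlation).

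Which changes go with loss of SIR2 was asked with set1htz1sir2 against set1htz1, where 374 genes were higher and 278 lower. LYS2 and URA1 also differed between these mutants, and marker genotypes are not given in the sources used here. Loss of SIR2 therefore cannot be separated from further strain differences in this comparison. The most higher were YNL337W (2.01 ± 0.18), YNR077C (1.73), YFL063W (1.66), SPL2 (1.64), CSS1 (1.59), YHR214W (1.56), YAL069W (1.53) and YHR214W-A (1.4975). Several of them belong to repeated families at chromosome ends and are uncertain as single genes. The most lower were SAG1 (-5.31 ± 0.18), AFB1 (-4.99), LIF1 (-4.98), YLR041W (-4.02), URA1 (-3.54), MDH2 (-2.97), STE4 (-2.83) and the meiotic telomere gene NDJ1 (-2.75). Haploid-specific genes (10 of 11, also over the list alone, median -1.44, adjusted p = 9.7e-16, and adjusted p = 0.0033 with an estimated correlation) and pheromone response genes (7 of 13, also over the list alone, median -0.60, adjusted p = 0.010 with an estimated correlation) were lower. The latter had AGA1 at -2.69 and the fusion gene FUS1 at -1.87. The phosphate regulon was higher in the triple mutant than in the double (4 of 15 higher and 1 lower, 7 and 1 adjusted over the list alone, adjusted p = 0.040 with an estimated correlation), with the phosphate transporter genes PHO89 at 1.07 and PHO84 at 0.68.

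Ribosomal protein genes were higher in set1htz1sir2 than in set1htz1 (59 of 121 higher and 1 lower, 89 and 1 adjusted over the list alone, median 0.61, adjusted p = 0.22 with an estimated correlation), as were respiration genes (13 of 27, 16 adjusted over the list alone, median 0.53, adjusted p = 0.085 with an estimated correlation). Histone genes (4 of 8 higher, 5 adjusted over the list alone, HTA1 at 0.84 and HHF2 at 0.77), COS genes (5 of 9, 8 adjusted over the list alone, COS3 at 0.72) and ribosome biogenesis genes (4 of 58 higher and 1 lower, also over the list alone, NHP2 at 0.85) were shifted upward (adjusted p = 0.088, 0.092 and 0.34 with an estimated correlation). NAD and thiamine genes (5 of 18 lower, also over the list alone, BNA2 at -1.11 and TNA1 at -1.09), general stress genes (3 of 30 lower, also over the list alone, YGP1 at -1.41), galactose genes (1 of 6, 2 adjusted over the list alone, GAL3 at -1.36), iron genes (1 of 17, also over the list alone, FRE2 at -0.70) and glycolysis genes (1 of 10, also over the list alone, PFK1 at -0.74) were shifted downward. None of these held with an estimated correlation (adjusted p = 0.16, 0.35, 0.16, 0.44 and 0.34, in that order, with an estimated correlation). Here too the change fell with coding length (Spearman correlation -0.41 across genes). The count of 652 called genes dropped to 346 without set1htz1 replicate 3, to 352 without set1htz1sir2 replicate 1 and to 399 without its replicate 3, and quantile normalization left 241. The share that was higher, 57.4% as deposited, was 43.2% with quantile normalization, 43.4% of 624 genes with the length trend removed and 44.2% of 274 genes at adjusted p under 0.01 (limma).

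**Figure D3:**
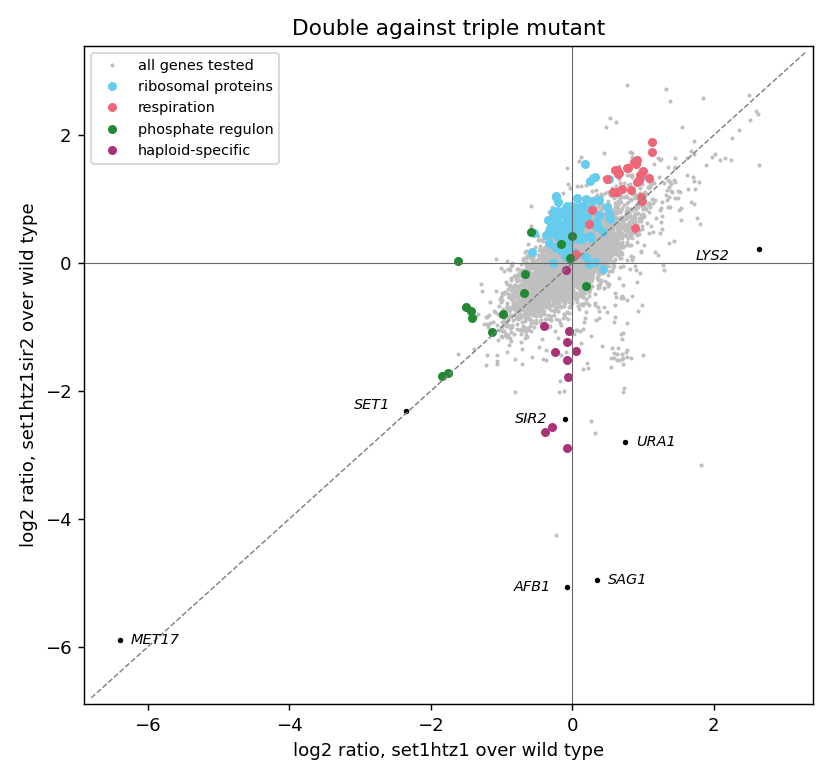
Log2 ratio of set1htz1sir2 over wild type against that of set1htz1 over wild type, 1 point per gene, with 4 gene groups coloured and the dashed line marking equal change. Haploid-specific genes, SAG1 (-4.96) and AFB1 (-5.06) lie below the line in the triple mutant, and respiration genes mostly above it.

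Of the 1352 genes that fell in set1htz1, 145 (10.7%) were higher in set1htz1sir2 than in set1htz1, against 98.2 for independent lists, and 136 genes that rose in set1htz1 were lower in set1htz1sir2, against 59.0. The 2 comparisons share the set1htz1 arrays, so chance in these arrays can raise the overlap. With the set1htz1 arrays split between the comparisons the overlap was 33 against 15.9 for independent lists, and 27 against 14.8 with the arrays exchanged. The phosphate-regulated genes SPL2, PHO89, PHM6 and PHO84 are among the 145 genes. SPL2 fell by 1.61 in set1htz1 and lay at 0.03 in set1htz1sir2, where PHO89 lay at 0.495. PHM6 and PHO84 remained at -0.68 and -0.75 in set1htz1sir2. Mitochondrial ribosomal protein genes made up a larger part than phosphate genes, such as MRPL20 (-1.29 in set1htz1, 0.98 in set1htz1sir2 against set1htz1). Short genes were higher in the latter comparison (Spearman correlation with coding length -0.413), so the overlap can hold part of that trend. Of the 145 genes, 99 were no longer called against wild type in the triple mutant, 25 were still lower and 21 were higher. Only 5 of the 145 were subtelomeric, against 33 of all 1352 that fell (odds ratio 1.503 against the other fallen genes, Fisher exact p = 0.39). By comparison, 874 genes fell in both mutants. The count of 145 was 61 without set1htz1 replicate 3, 70 without set1htz1sir2 replicate 1, 95 without its replicate 3 and 96 without its replicate 4.

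Genes near chromosome ends rose in all 4 mutants more often than other genes. In set1, 88 of 251 subtelomeric genes rose (35.1%, against 7.72% of the other genes; odds ratio 6.45, 95% interval 4.82 to 8.60, Fisher exact adjusted p = 4.8e-31), including HSP32 and the mannitol dehydrogenase gene DSF1 (1.495). In H3K4A 43 rose (17.1% against 2.90%; odds ratio 6.92, 4.67 to 10.1, adjusted p = 3.5e-18), including YAR068W (0.99). In set1htz1 119 rose (47.4% against 19.9%; odds ratio 3.63, 2.78 to 4.73), including YPS6 (1.72), and in set1htz1sir2 117 rose (46.6% against 23.0%; odds ratio 2.93, 2.24 to 3.81). Subtelomeric genes fell less often than others in set1htz1 (odds ratio 0.41) and set1htz1sir2 (0.47). Neither held at a change of at least 1.5-fold, where the odds ratios of set1htz1sir2 and set1 turned direction. In set1 the odds ratio of 0.49 passed (adjusted p = 0.014) but missed the threshold without replicates 1, 3 or 4 (0.66, 0.67 and 0.78). In H3K4A it was 0.65 (adjusted p = 1).

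As a list, subtelomeric genes were shifted upward with an estimated correlation in H3K4A (43 rose and 1 fell, 70 and 1 adjusted over the list alone, median 0.14, adjusted p = 0.037). The shift was lost in set1 (88 rose and 13 fell, 96 and 19 adjusted over the list alone, adjusted p = 0.063 with an estimated correlation), set1htz1 (119 and 33, 130 and 34 adjusted over the list alone, adjusted p = 0.092 with an estimated correlation) and set1htz1sir2 (117 and 37, 118 and 40 adjusted over the list alone, adjusted p = 0.15 with an estimated correlation). Between set1htz1 and set1 subtelomeric genes were no more often higher (odds ratio 0.97) or lower (0.70, adjusted p = 0.21) than other genes. In set1htz1sir2 against set1htz1 the odds ratio was 1.58 for higher genes (adjusted p = 0.047) and 1.38 for lower genes (adjusted p = 0.23). The former ranged from 1.68 to 3.70 with 1 array left out, highest without set1htz1 replicate 3, and its call was lost in 6 other settings, with odds ratios from 1.07 to 1.41. In H3K4A against set1 they were overrepresented among both higher (odds ratio 2.01, adjusted p = 0.014) and lower genes (3.50, adjusted p = 2.1e-06). The former missed the threshold without set1 replicates 2 or 4 (1.71 and 1.80) and without H3K4A replicates 1 or 3 (1.52 and 1.66).

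**Figure D4:**
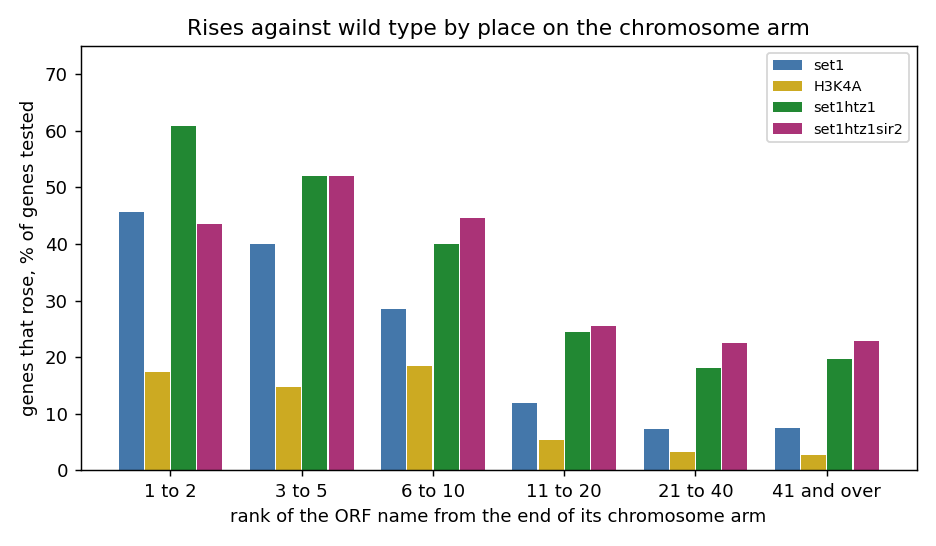
Share of tested genes that rose against wild type (percent) by the rank of their ORF name from the end of the chromosome arm, for each mutant. In set1 the share is 45.7% for the 2 outermost names, 28.5% for ranks 6 to 10 and 7.40% from rank 41 on.

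The SWR1 complex, which places H2A.Z in chromatin, did not pass the threshold in any comparison (11 genes measured, camera adjusted p from 0.072 to 0.85). Its lowest p were in set1htz1 (median -0.25, 5 genes fell and 1 rose, adjusted p = 0.072) and in set1htz1 against set1 (median -0.22, 4 lower and none higher, adjusted p = 0.082). The marker genes were not shifted as a list (6 measured, adjusted p from 0.060 to 0.87), though single members differed widely. Median and mean of this list differed in sign: 0.02 and -0.48 in set1htz1, 0.06 and -0.79 in set1htz1sir2, 0.085 and -0.31 between these mutants, and -0.06 and 0.20 in H3K4A against set1. MET17 was low in set1htz1 and set1htz1sir2, LYS2 was high in set1htz1 and TRP1 in H3K4A. Whether the strains differ by construction in these markers, or in URA1 outside this list, is not given in the sources used here, so the values of URA1 are not assigned to the mutations either. HIS3 averaged 0.92 ± 0.04 (SD, n = 4) in set1, 1.25 ± 0.27 in set1htz1 and 1.61 ± 0.12 in set1htz1sir2, against -0.02 ± 0.37 in H3K4A.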

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

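The tests of the mating-type pattern, and the tests of ribosomal protein genes that take the dye into account, were chosen only after the result was seen.

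Alpha-specific and haploid-specific genes were lower in set1htz1sir2, where a culture of the opposite mating type would show a-specific genes high. The 3 measured a-specific genes (STE2, STE6 and BAR1) had a median of -0.0475, which argues against it for these genes. The other a-specific genes of the list had no value in this mutant. Expression of the silent mating loci through loss of SIR2, the biological explanation the design gives, would raise probes inside and beside these loci: the median of 15 probes was 0.145, above that of 90.9% of 10000 random sets, with 7 higher, among them YCL074W (array mean 3.06), YCL076W (2.37) and YCR097W-A (3.29, SD 1.10, n = 3), and 5 lower, among them CHA1 (-1.60). HMLALPHA1 (-2.01) and HMLALPHA2 (-0.10), which lie in HML and have copies at MAT in alpha cells, were not among the 15. A median over probes that go both ways decides little, these probes were chosen after their values were seen and the 16 probes of the lists fixed before had a median of -0.09, which leaves that explanation open. A diploid culture with both mating types could also lower these genes, and the median of 0.145 does not separate it from expression of the silent loci.

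Ribosomal protein genes were higher in set1htz1sir2 than in set1htz1. Coding length does not account for it: their median exceeded that of genes of the same length by 0.49, while the matched genes had a median of 0.085. The 95% interval of 0.41 to 0.54 came from resampling genes and holds no spread between arrays. The planned exact permutation test of the array medians gave p = 0.114, but it leaves in the dye, which alternates in both groups alike. With the mean of each dye taken out the exact permutation p was 0.0286 for a difference of 0.63. Exchanging arrays only within a dye gave an exact permutation p of 0.0556, the lowest that 36 arrangements allow. Within each dye the groups did not overlap, with smallest gaps of 0.695 in Cy5 and 0.48 in Cy3. As only a test chosen after the result was seen passed, variation between arrays stays undecided. The array medians were 1.005, 0.25, 1.05 and 0.26 in set1htz1sir2 and 0.31, -0.25, 0.20 and -0.23 in set1htz1.

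Subtelomeric genes rose more often than others in set1 and in H3K4A. Cross-hybridisation within the PAU and COS families does not account for it, since without these families 74 of 227 rose in set1 and 32 of 227 in H3K4A, with lower 95% bounds of the odds ratio of 4.28 and 3.60 (odds ratios 5.84 and 5.61). Coding length does not either: the share that rose exceeded that of length-matched genes elsewhere by 28.4 percentage points (22.3 to 34.7) in set1 and 16.04 (11.02 to 21.5) in H3K4A, among the 219 of 251 genes with a known length. Cross-hybridisation in other repeated families was not tested, as probe sequences are unknown. Loss of H3K4 methylation, shared by both mutants by design, is the biological explanation the design gives. It was not tested, nor was it tested whether the same subtelomeric genes rose in both. In H3K4A against set1 subtelomeric genes were overrepresented among both lower (odds ratio 3.50) and higher genes (2.01). Some of them therefore differed between the mutants, whose RNA input may also differ.

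Whether any parting of the arrays would call as many genes was tested for the comparisons between mutants. Of the 35 ways to part 8 arrays into 4 and 4, only 1, the real one, called as many genes in each comparison: 995 in set1htz1 against set1 (next 9), 652 in set1htz1sir2 against set1htz1 (next 1) and 386 in H3K4A against set1 (next 184). Partings that mix the mutants count any difference between them as spread, which lowers their counts. The test therefore cannot decide between the mutations, other strain differences and RNA input as the source of the calls.

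Single arrays far from the other 3 of their group, by Dixon's 95% value, were found for 28 of 423 groups of named genes (6.62%), where chance gives about 1 in 20. In set1 these were NDE1 at -0.79 and MET3 at 0.06 on replicate 1, RNR4 at 0.30 and SWD1 at -0.62 on replicate 2, COX9 at -0.60 on replicate 3 and HOR7 at 0.60 on replicate 4. In H3K4A they were TRP1 at 1.89, RTN2 at 1.28 and HHF2 at 0.25 on replicate 1 and RNR2 at 0.37 on replicate 4. In set1htz1 they were PHO11 at -0.84 and SWD3 at -1.60 on replicate 1, MET17 at -5.64, GAL1 at 1.22 and YAL069W at -0.20 on replicate 2, CAR2 at 1.59 and AGA1 at 1.36 on replicate 3, and UTP22 at -0.97 and FUS1 at 0.07 on replicate 4. In set1htz1sir2 they were PRX1 at 1.14 and SAG1 at -4.64 on replicate 1, SET1 at -2.64, THI5 at 2.37, COS1 at 1.36, MET17 at -6.64 and YLR041W at -4.06 on replicate 3, and NHP2 at 0.21 on replicate 4. In the 4 cases of MET17, SAG1 and YLR041W the array differs from 3 equal values by a single step of 0.01 in the ratio, so the rounding of the deposited ratios sets their distance and they mark no unusual array. Replicate 1 of set1htz1 had 5385 entries with a value, against 5771, 5798 and 5782 on the other arrays of its group.

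Some genes lay far from 0 in 1 mutant but outside the test, because another group lacks them. Mean log2 ratios were 2.74 for YDR008C in H3K4A, and 2.73 for ATP1, -2.94 for HTZ1 and 2.14 for SPR2 in set1htz1. The ORF name YDR008C is next to that of the marker gene TRP1 (YDR007W), so its value is not assigned to the histone mutation either. In set1htz1sir2 they were 3.06 for YCL074W, 2.37 for YCL076W, 3.29 for YCR097W-A, 2.67 for YOL166C, -2.26 for MATALPHA1, -4.85 for STE3 and -6.64 for MF(ALPHA)1.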

How the results depend on the processing

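A dye term for each group, leaving out z entries, removing a coding-length trend and leaving out PAU and COS genes were chosen only after the data were seen. Across settings 105 counts of called genes stayed within 1.5 times and 33 did not. List tests kept direction and call 1394 times, lost the call 138 times and reversed 1 time. Named genes kept both 6760 times, lost the call 284 times, gained it 107 times and reversed 11 times. Odds ratios kept both 268 times, lost the call 22 times, gained it 5 times and reversed 20 times. Odds ratios for rises of subtelomeric genes against wild type held in every setting. The shift of these genes as a list was lost with an estimated correlation in set1, set1htz1 and set1htz1sir2. Stricter thresholds lower counts by construction. Otherwise the cause was not tested. Signal over background was not available.

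Genes called under other settings: quantile normalization, 773 in H3K4A (216 as reported), 574 in set1htz1 against set1 (995) and 241 in set1htz1sir2 against set1htz1 (652). Without a dye term, 136 in H3K4A, 408 in set1htz1sir2 against set1htz1 and 212 in H3K4A against set1 (386). With arrays 1 and 2, and 3 and 4, averaged: 1558 in set1 (970), 452 in H3K4A, 1623 in set1htz1 against set1, 1200 in set1htz1sir2 against set1htz1 and 802 in H3K4A against set1. With only the arrays of the groups compared: 41 in H3K4A, 1319 in set1htz1sir2 against set1htz1 and 103 in H3K4A against set1. At adjusted p under 0.01 (limma): 482 in set1, 109 in H3K4A, 428 in set1htz1 against set1, 274 in set1htz1sir2 against set1htz1 and 141 in H3K4A against set1. With a change of at least 1.5-fold: 202 in set1, 80 in H3K4A, 859 in set1htz1 (2445), 1045 in set1htz1sir2 (2596), 533 in set1htz1 against set1, 405 in set1htz1sir2 against set1htz1 and 242 in H3K4A against set1. The 145 genes that fell in set1htz1 and were higher in set1htz1sir2 became 61, 94, 308, 300, 47 and 35 under these settings, in that order. With a dye term for each group they numbered 222, and 1222 genes were called in set1, 282 in H3K4A, 2699 in set1htz1, 2809 in set1htz1sir2, 1218 in set1htz1 against set1, 906 in set1htz1sir2 against set1htz1 and 559 in H3K4A against set1. The correlation of set1 and H3K4A was 0.172 for genes with values on all 16 arrays.

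Odds ratios of subtelomeric genes among falls in set1 were 0.596 (quantile), 0.578 (no dye term), 0.667 (groups compared only), 0.552 (all 16 arrays), 0.838 (adjusted p under 0.01, limma) and, reversed, 1.74 (1.5-fold). For the subtelomeric odds ratio, fell, H3K4A against wild type, they were 0.0561 (quantile) and, reversed, 1.502 (no dye term), 2.17 (0.01) and 1.39 (5 names). Falls at 1.5-fold: 0.880 in set1htz1 and 1.05 in set1htz1sir2. For the subtelomeric odds ratio, rose, set1htz1 against set1, they were 1.016 (pairs averaged), 1.04 (all 16 arrays), 1.017 (z entries out), 1.22 (5 names) and 1.204 (15 names). Falls: 1.07 (quantile), 0.568 (pairs averaged) and 1.12 (1.5-fold). Rises of set1htz1sir2 over set1htz1: 1.07 (pairs averaged), 1.21 (groups compared only), 1.31 (all 16 arrays), 1.24 (15 names), 1.21 (a dye term for each group) and 1.41 (PAU and COS out). Falls: 0.891 (quantile), 1.48 (groups compared only), 0.878 (1.5-fold) and 0.439 (5 names). Rises of H3K4A over set1: 1.16 (groups compared only), 1.61 (1.5-fold) and 1.45 (5 names).

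With 1 array left out the counts ranged from 595 to 953 in set1, 129 to 216 in H3K4A, 1928 to 2148 in set1htz1, 2079 to 2216 in set1htz1sir2, 655 to 987 in set1htz1 against set1, 346 to 548 in set1htz1sir2 against set1htz1 and 246 to 398 in H3K4A against set1. The overlap ranged from 61 to 133 and the correlation from 0.160 to 0.218. Odds ratios of rises against wild type ranged from 5.37 to 6.81 in set1, 5.98 to 8.82 in H3K4A, 2.74 to 3.75 in set1htz1 and 2.67 to 2.90 in set1htz1sir2. Other odds ratios ranged from 0.425 to 0.784 for falls in set1, 0.578 to 1.06 for rises and 0.557 to 0.930 for falls of set1htz1 over set1, 1.68 to 3.70 for rises and 0.901 to 1.79 for falls of set1htz1sir2 over set1htz1 and 1.52 to 2.16 for rises of H3K4A over set1. In H3K4A ribosomal protein genes ranged from -0.31 to 0.063, RPL37B from -0.56 to 0.081 (also with pairs averaged) and PGI1 from -0.0027 to 0.38. SIR2 ranged from -0.073 to 0.11 in set1htz1 against set1 and -0.14 to 0.047 in H3K4A against set1, and SET1 from -0.11 to 0.25 in set1htz1sir2 against set1htz1. None of these genes was called.

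With the array number as a replicate block in place of the dye term, 890, 183, 2368 and 2543 genes were called in set1, H3K4A, set1htz1 and set1htz1sir2, 902 in set1htz1 against set1, 562 in set1htz1sir2 against set1htz1 and 317 in H3K4A against set1, with a correlation of 0.194. The genes that fell in set1htz1 and were higher in set1htz1sir2 numbered 115. Residuals of same-numbered arrays correlated between -0.527 and 0.293, and an array fitted best with its own number in 7 of 48 cases. Between set1htz1 and set1htz1sir2 they ranged from -0.061 to 0.293, against -0.246 to 0.152 for other numbers. Same-numbered arrays share a dye, and dye effects that differ between groups stay in the residuals. These correlations therefore cannot decide whether the numbers pair the arrays.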

Other observations

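The gene groups in the next paragraph were chosen only after their values were seen, and so were their tests.

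Mitochondrial ribosomal protein genes, which serve translation inside mitochondria, were low in set1htz1: 50 of 62 fell and none rose, with a median of -0.555 (limma camera adjusted p = 0.085 with an estimated correlation). In set1 24 fell and none rose (median -0.27, adjusted p = 0.096 with an estimated correlation), and in set1htz1sir2 13 rose and 14 fell (median -0.07, adjusted p = 0.89 with an estimated correlation). In set1htz1sir2 against set1htz1, 36 were higher and none lower (median 0.53, adjusted p = 0.042 with an estimated correlation). Short genes were higher in this comparison (Spearman correlation with coding length -0.413), and with the length trend removed the median was 0.37, with 22 higher and 1 lower. With that trend removed the median in set1htz1sir2 against wild type was -0.23, with 6 that rose and 25 that fell, so a return to wild-type level is not claimed. ORFs of Ty retrotransposons, whose copies the probes cannot separate, moved the other way in set1htz1 and in set1htz1sir2 against set1htz1. Both groups had negative medians in set1htz1sir2 and in H3K4A against wild type. In set1htz1 18 of 20 rose (median 0.66, adjusted p = 0.19 with an estimated correlation) and in set1htz1sir2 18 fell and 1 rose (median -1.455, adjusted p = 0.11 with an estimated correlation). In set1htz1sir2 against set1htz1, 18 were lower (median -2.13, adjusted p = 0.041 with an estimated correlation), and in H3K4A 9 fell (median -0.53, adjusted p = 0.096 with an estimated correlation).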
